A study of Mus musculus with 9 samples.

How the data were processed

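RNA-seq libraries of sorted TCRβ+ CD69+ CD24+ CD4+ CD8+ thymocytes from WT (3 samples) and SRSF1KO (2 samples) mice were used. Per the labels, RNA was isolated with a column kit and libraries were built by the Smart-seq2 protocol. The deposited table gives raw counts of reads per gene, not normalised, for 53715 versioned Ensembl mouse gene IDs. The submitters' processing notes name FastQC 0.11.5, cutadapt 1.17, Trim Galore, HTSeq 0.6.1, DESeq2 1.20.0, Bowtie2 2.1.0 and HOMER 4.9.1 and the genome build mm10, without saying which tool served which assay. The aligner of the RNA-seq reads, the gene annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be told apart. The 4 CLIP-seq samples were not analysed here. Groups were taken from the genotype and titles in the labels.

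Library totals were between 36026006 and 38985285 counts, so depth varied little between groups. No pair of libraries agreed within sampling noise. On a log scale the SRSF1KO libraries correlated with each other at 0.923 (Pearson), against 0.942 to 0.951 for WT pairs. Pairs of an SRSF1KO and a WT library correlated at 0.920 to 0.930, so on this measure the SRSF1KO libraries agreed no better with each other. By chi-square per degree of freedom they were closer to each other (55.5) than to any WT library (77.4 to 134). The IDs were matched to gene symbols in a names table: 53620 matched, 51464 of them also by version, 95 had no symbol, and 94 symbols belonged to more than 1 ID. IDs without a symbol held under 0.0053% of the counts in each library. Coordinates came from the RefSeq table of GRCm38.p6, the assembly that mm10 stands for, and 87.6% of tested genes had them. No genome sequence was used, and GC content was not checked.

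Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest), after TMM normalisation and the default filterByExpr filter, which left 17351 genes. The model held the group as its only term. The p-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called. All tests were two-sided unless stated. The common biological coefficient of variation was 0.494. Standard errors were derived from the log2 fold change and the F statistic. Levels are TMM-normalised CPM, given as mean ± SD with n = 3 for WT and n = 2 for SRSF1KO.

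A total of 34 gene lists were fixed before the data were examined and tested with camera from limma 3.58.1, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 34 lists. Beside it stand camera with an estimated correlation and fry. No list call held with an estimated correlation, and with fry the CD8 lineage list alone passed (adjusted p = 0.0202). Sex-linked genes were read only as counts per library.

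Named genes followed a rule fixed in advance. It took Srsf1, the gate genes Cd4, Cd8a, Cd69, Cd24a, Trbc1 and Trbc2, and Irf7 and Il27ra in every case. It added up to 10 called genes with the largest rise and 10 with the largest fall, with a mean of at least 5 CPM and groups that do not overlap, without receptor segments, predicted genes, pseudogenes and sex-linked genes. For each list it added up to 4 called members with the largest change, or members with the smallest p up to 2.

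The scripts were tested on simulated counts with the means, library sizes and dispersions of these samples. Genes were drawn independently, unlike the real lists, and changed genes were taken from those of at least 5 CPM. Of 100 genes changed 2-fold, edgeR recovered 68% and DESeq2 77%, and of 100 genes changed 4-fold they recovered 82% and 91%. Among 16376 simulated genes tested, edgeR made 17 false calls, DESeq2 74 and limma-voom 11. The interferon response list was shifted by −0.6 on the log2 scale and left out of the false calls.

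The alternatives were scaling by DESeq2's size factors or the upper quartile, no filter on low counts, a minimum mean of 5 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, and leaving out each library in turn. A term for sex and a maturation list without class I genes were added after the data were examined. Where a library is left out of SRSF1KO, the remaining one is assumed to vary like the WT libraries.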

Results

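The series profiled gene expression in mouse thymocytes that lack SRSF1, a serine/arginine-rich RNA-binding protein that takes part in constitutive and alternative splicing of pre-mRNA. Thymocytes were sorted by flow cytometry for surface TCRβ, CD69, CD24, CD4 and CD8, a gate that holds CD4 and CD8 double-positive cells after T cell receptor signalling has begun. The C57BL/6 donors were 6 to 8 weeks old. Bulk RNA-seq libraries made by the Smart-seq2 method, which amplifies full-length cDNA from polyadenylated RNA, were deposited for 3 WT and 2 SRSF1KO samples. The libraries held between 36026006 and 38985285 gene-assigned counts each. The labels do not say whether the replicates came from separate animals, and the p-values measure only the spread between these 5 samples. Sex-linked transcripts differed between libraries within each group, so neither group came from a single animal, while the spread between WT replicates 1 and 3, of the same sex pattern, may be technical. A further 4 CLIP-seq samples, 2 with an SRSF1 antibody and 2 with control IgG, are listed in the series and were not analysed here.

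The targeted gene was measured first in each library. Srsf1 (ENSMUSG00000018379.17, chromosome 11, 88046499 to 88053757, GRCm38) stood at 96.9, 122.7 and 103.1 CPM (normalised counts scaled to a common library size) in WT replicates 1, 2 and 3, and at 42.6 and 30.9 CPM in SRSF1KO replicates 1 and 2. Its level fell from 107.5 ± 13.5 CPM (SD, n = 3) to 36.8 ± 8.25 CPM (SD, n = 2), a log2 fold change of −1.55 ± 0.19 (SE; edgeR quasi-likelihood test, adjusted p = 0.0483). The counts cover the whole gene, so the remaining reads cannot be assigned to deleted or retained exons. Omitting any of the 5 libraries moved the adjusted p above the threshold, to between 0.0509 and 0.220, with an Srsf1 log2 fold change between −1.80 and −1.32.

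The comparison of SRSF1KO with WT asked which transcripts depend on SRSF1 in these cells. Genes of the interferon response, of MHC class I antigen presentation and of the mature T cell programme were lower in SRSF1KO, and genes typical of double-positive cells before selection were higher as a group. These 4 list calls rest on a preset correlation: with an estimated correlation the adjusted p was 0.339, 0.212, 0.212 and 0.379, and 2, 5, 6 and 0 members passed singly. H2-Q7, H2-K1, H2-D1 and B2m are counted in both the class I and the maturation list. Slfn1, a Schlafen family gene expressed in T cells, fell from 161.8 ± 9.23 to 33.0 ± 5.34 CPM, and the cytokine receptor gene Il27ra fell from 281.8 ± 4.9 to 115.8 ± 0.751 CPM (SD, n = 3 and n = 2). The classical MHC class I gene H2-K1 fell from 1953 ± 42.6 to 777 ± 208 CPM. Cpt1a, which encodes the carnitine palmitoyltransferase that controls entry of fatty acids into mitochondria, rose from 21.5 ± 1.90 to 63.6 ± 4.12 CPM.

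Of 17351 genes tested, 37 were lower and 9 were higher in SRSF1KO (edgeR, adjusted p under 0.05), while 1466 lower and 1024 higher genes passed an unadjusted p of 0.05. In all 46 called genes the SRSF1KO libraries lay on one side of the WT libraries. That was so for 32.9% of all tested genes, against 20% by chance for 3 libraries against 2. The number of calls depended on the test: DESeq2 called 633 lower and 383 higher genes, among them all 46, and edgeR called 0 genes when WT replicate 1, 2 or 3 was left out, with 1903, 2005 and 2079 genes at an unadjusted p under 0.05. Scaling by DESeq2's size factors left 7 lower and 3 higher genes, a share of higher calls of 30% against 19.6%, and leaving out SRSF1KO replicate 1 left 8 lower and 3 higher, against 67 and 21 without SRSF1KO replicate 2.

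The largest falls among called genes with a mean of at least 5 CPM were those of Ccdc102a, Rflnb, Tmie, Slfn1, Adgrg5, H2-Q7, Slc15a1, Clcf1, Cd7 and Ifi27l2a. Ccdc102a fell from 33.0 ± 4.10 to 3.98 ± 2.25 CPM, a log2 fold change of −3.05 ± 0.39 (SE, adjusted p = 0.0483). Tmie fell by 2.63 ± 0.17 on the log2 scale (adjusted p = 0.0066) and Slfn1 fell by 2.30 ± 0.14 (adjusted p = 0.0066). Rflnb fell by 2.64, the adhesion G protein-coupled receptor gene Adgrg5 by 2.27, the peptide transporter gene Slc15a1 fell by 2.09 and the cytokine gene Clcf1 by 2.05, each with an adjusted p of 0.0483. Adgrg5 and Ccdc102a are neighbours on chromosome 8, at 94921811 to 94943293 and 94902869 to 94918098. Only 8 genes met the conditions for the largest rises. Slfn4, a Schlafen gene of the same chromosome 11 cluster as Slfn1, rose from 0.522 ± 0.280 to 20.1 ± 3.84 CPM (log2 fold change 5.26 ± 0.47, adjusted p = 0.0238). Cpt1a rose by 1.56 ± 0.16 (adjusted p = 0.0401), the linker histone gene H1f0 by 1.52 ± 0.14 (adjusted p = 0.0293) and the core histone gene Hist2h2be by 1.46 ± 0.18 (adjusted p = 0.0483). Hivep3 (0.85), Slc9a9 (0.75), Leng8 (0.72) and the arginine/serine-rich protein gene Rsrp1 (0.62) rose by smaller log2 fold changes. Reads of Slfn1 and Slfn4, and those of H2-Q7 and its close relatives, can be split between paralogs by the counting, so these 3 values are less certain. Ifi27, also called lower, lies within the coordinates of Ifi27l2a on chromosome 12, so the value of Ifi27l2a is less certain too.

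**Figure D1:**
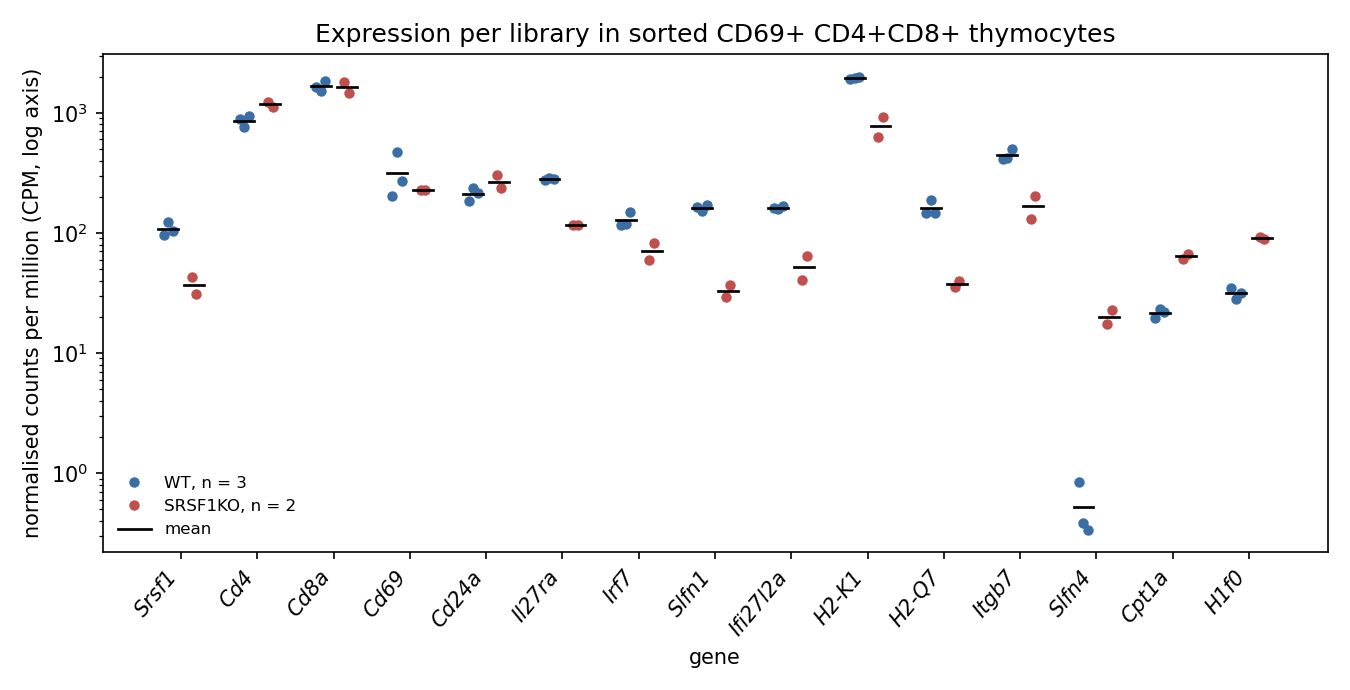
Normalised counts (CPM) on a log axis for 15 genes in each WT (blue, n = 3) and SRSF1KO (red, n = 2) library, with a black line at each group mean. Srsf1 lies at 30.9 and 42.6 CPM in SRSF1KO against 96.9 to 122.7 CPM in WT, while Cd8a overlaps between the groups and Slfn4 rises from under 1 CPM to 20.1 CPM.

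No gene of the sort gate passed over all genes tested with edgeR. Cd8a stood at 1664 ± 156 CPM in WT and 1639 ± 256 CPM in SRSF1KO (log2 fold change −0.02 ± 0.12, adjusted p = 0.972). Cd4 stood at 860 ± 84.5 and 1174 ± 78.4 CPM (0.45 ± 0.11, adjusted p = 0.136), Cd69 at 314 ± 138 and 227 ± 1.61 CPM (−0.47 ± 0.31, adjusted p = 0.561) and Cd24a at 212 ± 27.0 and 268 ± 47.1 CPM (0.34 ± 0.15, adjusted p = 0.364). For Cd4 the SRSF1KO libraries, at 1229 and 1118 CPM, lay above the WT libraries, at 767 to 932 CPM. Cd69 stood at 203, 469 and 271 CPM in WT replicates 1, 2 and 3, so its WT mean leans on replicate 2. Trbc1 (0.08 ± 0.10, adjusted p = 0.821) and Trbc2 (0.20 ± 0.10, adjusted p = 0.426), the constant segments of the TCRβ chain, likewise did not pass. Over the 12 gate genes tested, among them Trac at −0.24 ± 0.08 (adjusted p = 0.230), the median log2 fold change was −0.03 (camera adjusted p = 0.973). When adjusted over the list alone, 1 gate gene was higher and 0 lower. Over all genes, 1 was called higher with DESeq2, without the filter on low counts and at a mean of at least 5 CPM.

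Interferon-stimulated genes were lower as a group. Of 67 genes of the type I interferon response, 58 had a negative log2 fold change, with a median of −0.63 (camera, preset correlation, adjusted p = 5.7e-20). With a correlation estimated from the 5 libraries the adjusted p was 0.339. The median was −0.39 without SRSF1KO replicate 1. Slfn1 and Ifi27l2a, both with less certain read assignment, passed over all genes tested, and 23 members were lower and 0 higher when adjusted over the list alone. Ifi27l2a, which responds to interferon, fell from 161.6 ± 3.83 to 52.5 ± 17.2 CPM (log2 fold change −1.62 ± 0.20, adjusted p = 0.0483). Irf7, the transcription factor that amplifies type I interferon responses, stood at 128.2 ± 18.0 CPM in WT and 71.0 ± 15.9 CPM in SRSF1KO, and its log2 fold change of −0.85 ± 0.18 did not pass (adjusted p = 0.120). For the 29 receptor and signalling components of the interferon pathway the median was −0.15 (camera adjusted p = 0.159), with Socs1 at 0.57 and Ifngr1 at 0.51, neither past the test, and −0.25 without SRSF1KO replicate 2.

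MHC class I genes were lower as a group. The 23 genes of class I presentation had a median log2 fold change of −0.60, with 21 members negative (camera adjusted p = 2.5e-26). The adjusted p was 0.212 with an estimated correlation. Adjusted over the list alone 17 members were lower and 0 higher, and 5 passed over all genes tested. H2-K1 (chromosome 17, 33996012 to 34000619) fell by 1.33 ± 0.16 on the log2 scale, H2-D1 by 1.02 ± 0.13 and the proteasome activator gene Psme2 by 0.82 ± 0.10 (SE; adjusted p = 0.0483 for each). H2-Q7, a nonclassical class I gene, fell by 2.1 ± 0.16 (adjusted p = 0.0095).

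Genes that are switched on as thymocytes mature were lower in SRSF1KO, and genes of the earlier double-positive stage were higher. Among 55 maturation genes the median log2 fold change was −0.41, with 44 members negative (camera adjusted p = 3.3e-20). The call was lost with an estimated correlation (adjusted p = 0.212). Of these members 6 were lower over all genes tested, among them H2-Q7, H2-K1, H2-D1 and B2m, which the class I list also holds. When adjusted over the list alone, 25 were lower and 3 higher. Itgb7, an integrin subunit used in lymphocyte homing, fell from 445.9 ± 47.7 to 167.7 ± 51.1 CPM, and Ms4a4b, a membrane protein gene of mature T cells, fell from 367.0 ± 29.5 to 168.9 ± 25.4 CPM (adjusted p = 0.0483 for both). The list shares 7 members with the class I list. Without them the remaining 48 genes had a median of −0.36 (camera adjusted p = 1.5e-11, and an adjusted p of 0.248 with an estimated correlation), a subset chosen after seeing the data. The 33 pre-selection genes had a median of 0.43, with 27 members positive (camera adjusted p = 8.1e-09). Their adjusted p was 0.379 with an estimated correlation, and the median was 0.23 without SRSF1KO replicate 1. None passed over all genes tested, while 14 were higher and 1 lower when adjusted over the list alone. Arpp21 stood at 343.2 ± 39.3 CPM in WT and 642.2 ± 170 CPM in SRSF1KO (adjusted p = 0.0957), and Dntt, the terminal transferase of TCR rearrangement, at 953.3 ± 92.1 and 1618 ± 470 CPM (adjusted p = 0.127).

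The libraries differed in sex-linked transcripts within each group. WT replicate 2 and SRSF1KO replicate 1 held 5803 and 5699 counts of the Y-linked gene Ddx3y, against 23 to 141 in the others, and 1369 and 282 counts of Xist against 14784 to 21400. Between the libraries of the female pattern (1 SRSF1KO, 2 WT) the median difference of the interferon response genes was −0.36, and between those of the male pattern (1 of each) it was −0.93. The corresponding medians were −0.62 and −0.70 for class I genes, −0.43 and −0.62 for maturation genes, and 0.20 and 0.61 for pre-selection genes. With sex as a term in edgeR, an alternative chosen after seeing the data, 5 genes were lower and 0 higher, with 2269 genes at an unadjusted p under 0.05. The libraries also differed in how their counts were distributed, in step with the groups and so with the falls of the interferon, class I, maturation and ribosomal protein lists. The 10 genes with most counts took 6.77%, 8.27% and 8.15% of the counts in WT replicates 1, 2 and 3 and 10.2% and 9.92% in SRSF1KO replicates 1 and 2. Gm26917 took 1.84%, 2.69% and 2.98% against 4.47% and 4.14%, and CT010467.1 took 0.852%, 1.33% and 1.06% against 1.56% and 1.42%, both chosen after their values were seen. Whether these shares bear on the list values was not tested.

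Lineage genes differed in direction. The 18 CD8 lineage genes had a median log2 fold change of −0.87, with 15 negative (camera adjusted p = 3.3e-09, and an adjusted p of 0.212 with an estimated correlation), and 7 were lower and 1 higher when adjusted over the list alone. Cd7 fell from 86.4 ± 14.2 to 27.9 ± 7.24 CPM and Ctsw, a cathepsin gene of cytotoxic lymphocytes, from 323.3 ± 29.0 to 121.1 ± 32.0 CPM (adjusted p = 0.0483 for both). The CD8 list shares 2 members with the γδ T and NK cell list and 1 each with the interferon, maturation, pre-selection and agonist lists. Of its members, Nkg7 stood at −2.14, and Klrd1 and Cd8b1, chosen after their values were seen, at −1.86 ± 0.51 and −0.06 ± 0.13, with Cd8a at −0.02, none of the 4 past the test. The 19 CD4 lineage genes had a median of 0.42, with 15 positive (camera adjusted p = 6.3e-05, and an adjusted p of 0.248 with an estimated correlation). Of these, 10 were higher and 1 lower when adjusted over the list alone and 0 passed over all genes tested, Cd28 at 0.58 and Tcf7 at 0.41 among them (adjusted p = 0.0978 and 0.118). Over 43 genes of positive selection and TCR signalling the median was 0.00 and the mean −0.13 (camera adjusted p = 0.406, in the upward direction), and Hivep3, a zinc finger gene, was the only member that passed. Of 37 genes of cytokine receptors and their signalling the median was −0.18 (camera adjusted p = 0.0087, and an adjusted p of 0.513 with an estimated correlation). Il27ra (chromosome 8, 84030286 to 84042600), a subunit of the interleukin-27 receptor, fell by 1.28 ± 0.09 on the log2 scale (adjusted p = 0.0083), and Ltb stood at 657.8 ± 14.5 and 409.8 ± 60.4 CPM (adjusted p = 0.0641). The cytokine receptor call was lost without WT replicate 3 (median −0.10) or SRSF1KO replicate 1 (median −0.03), and at a mean of at least 5 CPM the median was −0.12. Over 32 genes of chemokine receptors and trafficking the median was −0.17 (camera adjusted p = 0.0212, and an adjusted p of 0.426 with an estimated correlation), with Itgb7 past the test and S1pr1, the receptor used in thymic egress, at −0.99 ± 0.18 (adjusted p = 0.0917). That call was lost without WT replicate 3 (median −0.13) or SRSF1KO replicate 1 (median −0.14), and at a mean of at least 5 CPM (median −0.09, adjusted p = 0.125). The 23 agonist-selected T cell genes had a median of −0.64 (camera adjusted p = 0.0306, and an adjusted p of 0.339 with an estimated correlation), with Xcl1 at −2.23 and Tnfrsf9 at −0.89, neither past the test. The agonist call was lost without WT replicate 1 (median −0.57), WT replicate 3 (−0.69) or SRSF1KO replicate 1 (−0.51), with limma-voom (adjusted p = 0.0663) and at a mean of at least 5 CPM (adjusted p = 0.232).

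Splicing factor lists had medians near 0, which does not show that single members were unchanged. DESeq2 called 0 SR genes higher and 3 lower, and 1 core spliceosome gene higher and 2 lower. Of hnRNPs and other regulators it called 3 higher and 0 lower, and of decay and junction genes 1 higher and 0 lower. The 30 SR proteins and their kinases had a median log2 fold change of 0.05 (camera adjusted p = 0.739), with Rsrc1 at −0.70 and Srpk1, an SR protein kinase, at −0.58 (adjusted p = 0.150 and 0.0964). The 48 core spliceosome genes had a median of −0.02 (camera adjusted p = 0.739), with Snrpa1 at −0.77 and Rbm25 at 0.63 (adjusted p = 0.0642 and 0.0568). With 1 library left out the core spliceosome median lay between −0.062 and −0.0065, and that of SR proteins was 0.022 without SRSF1KO replicate 1. For 43 hnRNPs and other splicing regulators the median was 0.06 (camera adjusted p = 0.0282, and an adjusted p of 0.339 with an estimated correlation), with Mbnl2 at 0.41 and Hnrnpm at 0.36, neither past the test. The hnRNP call was lost without WT replicate 1 (median 0.03), SRSF1KO replicate 1 (0.10) or SRSF1KO replicate 2 (0.02). The 27 genes of nonsense-mediated decay and the exon junction complex had a median of −0.01 and a mean of 0.03 (camera adjusted p = 0.480), with Thoc2 at 0.41 and Rnps1 at −0.31. Gene-level counts do not show exon inclusion.

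Ribosomal protein genes were lower as a group. Of 77 cytosolic ribosomal protein genes 75 had a negative log2 fold change, with a median of −0.41 (camera adjusted p = 2.6e-31). With an estimated correlation the adjusted p was 0.379. Over all genes tested 5 were lower, and 57 were lower and 0 higher when adjusted over the list alone. Rpl35 fell from 218.4 ± 13.8 to 128.4 ± 1.91 CPM, Rpl36 from 301.3 ± 16.4 to 182.2 ± 4.45 CPM, Rps18 from 593.3 ± 30.1 to 367.0 ± 5.56 CPM and Rpl32 from 731.6 ± 45.3 to 453.1 ± 1.10 CPM (adjusted p = 0.0483 for each). These genes have many processed pseudogenes that can take reads from them.

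**Figure D2:**
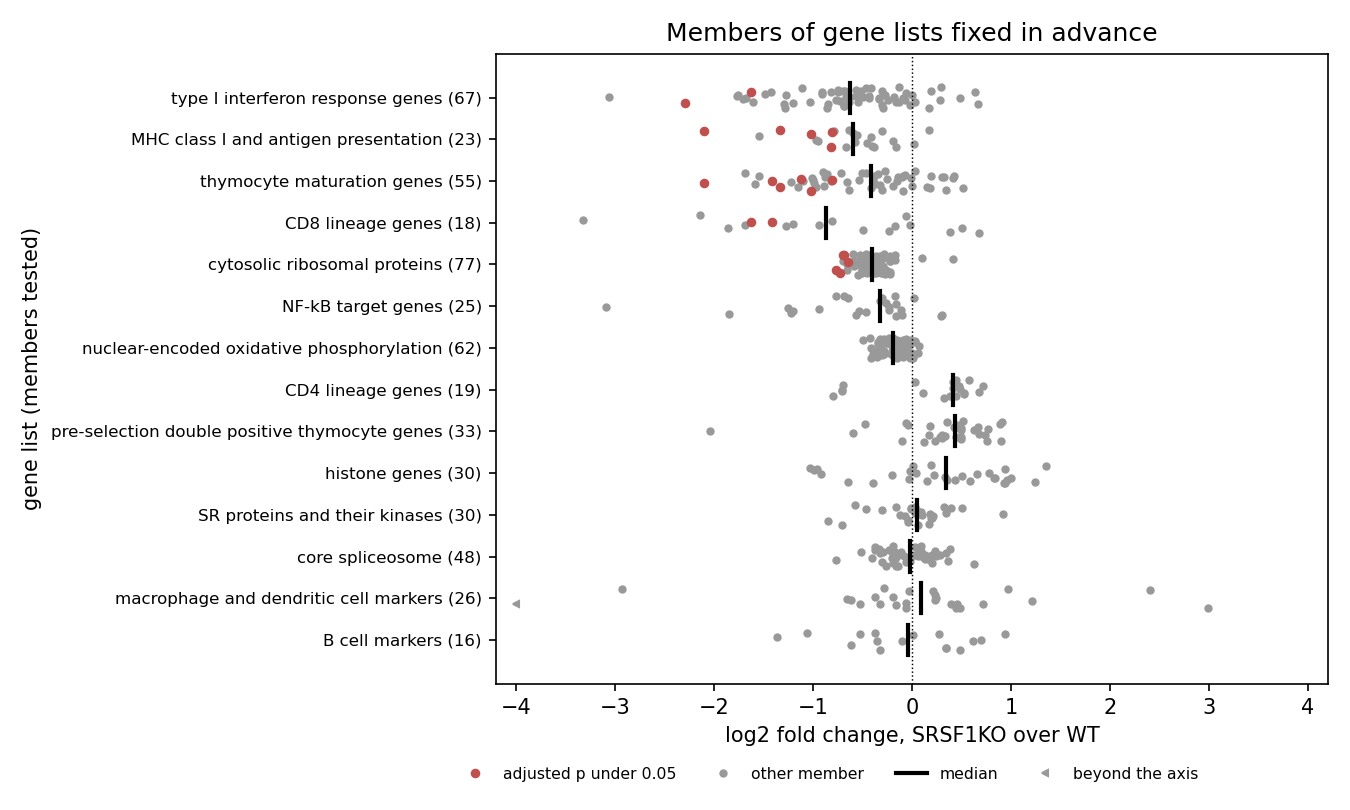
Log2 fold change of SRSF1KO over WT for each tested member of 14 gene lists (points, red where the adjusted p is under 0.05 over all genes), with the list median as a black line and 1 member beyond the axis drawn as a triangle. Medians lie at −0.63 for interferon response genes, −0.60 for class I genes and −0.41 for ribosomal proteins, against 0.43 for pre-selection genes and 0.05 for SR proteins.

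The 34 apoptosis regulators had a median log2 fold change of −0.13 (camera adjusted p = 0.236), with Fasl at −3.11 and Bmf at −1.13, neither past the test. The apoptosis median was −0.078 without WT replicate 1, −0.064 without WT replicate 3, −0.048 at a mean of at least 5 CPM and −0.080 with limma-voom. The 31 p53 targets had a median of 0.18 (camera adjusted p = 0.0310, and an adjusted p of 0.426 with an estimated correlation), with the class I transporter gene Tap1 at −0.64 and Ccng1 at 0.49. The 50 cell cycle genes had a median of 0.20 (camera adjusted p = 0.0179, and an adjusted p of 0.572 with an estimated correlation), with Ccnb1 at 0.76 ± 0.12 (adjusted p = 0.0660) and Aurka at 0.77 ± 0.18 (adjusted p = 0.129). Without SRSF1KO replicate 1 the medians of the p53 and cell cycle lists were 0.03 and 0.04 and both calls were lost. The p53 call was also lost without WT replicate 1 (median 0.15) and the cell cycle call without WT replicate 3 (median 0.12). The p53 median was 0.28 without WT replicate 3 or SRSF1KO replicate 2.

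Markers of cell types outside the gate were measured in the same libraries. No such list passed the main test: the camera adjusted p was 0.973 for 16 B cell markers (median −0.04, mean −0.06, test direction upward), 0.739 for 26 macrophage and dendritic cell markers (median 0.09, mean −0.05), 0.973 for 11 thymic stromal markers (median 0.18), 0.159 for 9 erythroid markers (median 0.69), 0.0837 for 20 double-negative thymocyte markers (median 0.31) and 0.614 for 19 γδ T and NK cell markers (median 0.29, mean −0.23). Without WT replicate 1 the medians of the double-negative and the γδ T and NK cell lists were 0.080 and 0.036, and without WT replicate 3 they were 0.53 and 0.54, with 0.15 for the γδ T and NK cell list without SRSF1KO replicate 1. Without SRSF1KO replicate 1 B cell markers stood at −0.34, macrophage and dendritic cell markers at −0.24, stromal markers at −0.52 and erythroid markers at −0.34. The double-negative list passed without the filter on low counts (adjusted p = 0.0242) and with limma-voom (adjusted p = 0.0479), and the erythroid list with the sex term (adjusted p = 0.0495). Cd74 stood at 230 ± 57.1 CPM in WT and 178 ± 46.1 CPM in SRSF1KO, and Ighm at 484 ± 29.3 and 614 ± 140 CPM. Several markers were low and differed in level: Xcr1 stood at 1.21 ± 0.417 CPM in WT and 0.014 ± 0.0198 CPM in SRSF1KO, Pdgfrb at 3.32 ± 0.410 and 0.140 ± 0.0796 CPM (log2 fold change −4.54 ± 0.74, adjusted p = 0.0660) and the globin gene Hba-a2 at 0.619 ± 0.382 and 6.31 ± 4.38 CPM (3.35 ± 0.77, adjusted p = 0.128). Siglech (0.97) and Cldn4 (1.45) likewise did not pass. Car2, an erythroid list member, stood at 15.1 ± 4.33 and 5.61 ± 0.0256 CPM. The γδ T and NK cell list holds Nkg7, at 177 ± 10.4 CPM in WT and 40.1 ± 21.4 CPM in SRSF1KO (log2 fold change −2.14 ± 0.31, adjusted p = 0.0568), and Il2rb at −1.09 ± 0.19 (adjusted p = 0.0816). Among the double-negative markers Dtx1 stood at −0.98 and Trdc, the TCRδ constant segment, at 0.74, neither past the test.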

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

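The sex term and the maturation list without class I genes were chosen after the data were seen, the other alternatives before. All 46 called genes kept their direction in every alternative in which they were tested. Counts of lower and higher genes were 35 and 9 with upper-quartile scaling, 7 and 3 with DESeq2's size factors in edgeR, 346 and 198 without the filter, 233 and 143 at a mean of at least 5 CPM, 633 and 383 with DESeq2, 71 and 23 with limma-voom, and 5 and 0 with the sex term. Most calls lay just under the threshold, at an adjusted p of 0.0483. Leaving out 1 library gave 0 to 67 lower and 0 to 21 higher genes. Both counts were 0 without WT replicate 1, 2 or 3, and highest without SRSF1KO replicate 2. The cause was not tested for any of these changes. DESeq2 and limma-voom, run on all 5 libraries, shared 46 and 42 genes with the main calls.

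The replicate numbers 1 and 2 occur in both groups. Libraries of the same number deviated from their group means with correlations of −0.12 and −0.10 across genes, which gives no sign that the numbers pair them. A pairing cannot be excluded, since with 2 SRSF1KO libraries the deviations mirror each other, at 0.12 and 0.10 for the crossed pairs. Libraries of the same number also differed in sex pattern. With a replicate block edgeR called 0 higher and 0 lower genes, with a lowest adjusted p of 0.292 and 1640 genes at an unadjusted p under 0.05, and the Srsf1 log2 fold change was −1.59 (adjusted p = 0.314). The block also ended the calls of the cytokine receptor (adjusted p = 0.0938), trafficking (0.0642), agonist (0.104) and cell cycle lists (0.195, median 0.086), and the double-negative list passed (0.0271, median 0.56). The Srsf1 log2 fold change was −1.53 with DESeq2's size factors (adjusted p = 0.0515) and between −1.80 and −1.32 with 1 library left out. The adjusted p of Srsf1 ranged from 1.9e-12 to 0.314 over the alternatives.

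Medians of the interferon (−0.63), maturation (−0.41) and pre-selection (0.43) lists kept direction and call in every fit and lost the call with an estimated correlation and with fry, which leave the median as it is. The adjusted p was 0.339 and 0.123, 0.212 and 0.0650, and 0.379 and 0.180. With 1 library left out they ranged from −0.77 to −0.39, −0.54 to −0.40 and 0.23 to 0.57. Over 31 other lists, 374 of 465 alternatives kept direction and call, 50 lost the call, 5 gained it (3 of them the double-negative, 1 the erythroid and 1 the interferon signalling list, −0.25 without SRSF1KO replicate 2) and 36 reversed the sign, in 9 lists that were not called. Over the 88 named genes, 825 of 1139 kept both, 195 lost the call, 114 gained it and 5 reversed, in Trbc1 and Cd8a, not called.

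The reversed values, on the log2 scale, were as follows, and their cause was not tested. Positive selection stood at 0.015 with DESeq2's size factors and with DESeq2, 0.018 with the upper quartile, 0.0017 without the filter, 0.047 at 5 CPM and 0.017 with the sex term. Nonsense-mediated decay stood at 0.0089 with DESeq2's size factors and with DESeq2, 0.012 with the upper quartile, 0.010 at 5 CPM, 0.037 with the block and 0.0043 with the sex term. Without the filter B cell markers stood at 0.020, macrophage and dendritic cell markers at −0.016 and erythroid markers at −0.48. With the block cholesterol synthesis stood at 0.0093, gate genes at 0.027 and Cd8a at 0.044, and Cd8a at 0.0015 with the upper quartile. With the sex term macrophage and dendritic cell markers stood at −0.070 and stromal markers at −0.13. With 1 library left out the ranges were −0.18 to 0.084 for positive selection, 0.0058 to 0.068 for nonsense-mediated decay, −0.095 to 0.052 for glycolysis, −0.077 to 0.019 for cholesterol synthesis, −0.34 to 0.045 for B cell, −0.24 to 0.26 for macrophage and dendritic cell, −0.52 to 0.30 for stromal, −0.34 to 2.05 for erythroid markers, −0.12 to 0.084 for gate genes, −0.053 to 0.22 for Trbc1 and −0.19 to 0.15 for Cd8a.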

Other observations

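Of 30 histone genes 21 had a positive log2 fold change, with a median of 0.35 (camera adjusted p = 0.0029, and an adjusted p of 0.513 with an estimated correlation), and the call was lost without SRSF1KO replicate 1 (median 0.33). The median was 0.90 at a mean of at least 5 CPM and 0.23 without WT replicate 1. Hist1h1c stood at 34.9 ± 3.38 CPM in WT and 70.0 ± 5.01 CPM in SRSF1KO and Hist1h2bc at 12.9 ± 2.22 and 33.2 ± 4.23 CPM (adjusted p = 0.0601 and 0.0720). When adjusted over the list alone, 3 histone genes were higher and 0 lower. Of 25 NF-κB targets 22 were negative, with a median of −0.32 (camera adjusted p = 8.5e-06, and an adjusted p of 0.339 with an estimated correlation), among them the signalling adaptor gene Traf1 at −1.25 ± 0.22 (adjusted p = 0.0746) and Ltb at −0.68. Of 24 immediate early and heat shock genes 21 were negative, with a median of −0.47 (camera adjusted p = 1.3e-05, and an adjusted p of 0.426 with an estimated correlation), with Dnajb1 at −0.45 and Hspe1 at −0.56. That call was lost without SRSF1KO replicate 1 (median −0.28).

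Nuclear-encoded genes of oxidative phosphorylation had a median log2 fold change of −0.19, with 55 of 62 negative (camera adjusted p = 5.7e-06, and an adjusted p of 0.375 with an estimated correlation), and 0 passed singly, Ndufb10 at −0.49 and Atp5d at −0.41 among them. Genes of short genomic span were lower in general, with medians of −0.14 in the shortest bin of genes and −0.11 in the next. How much of the oxidative phosphorylation median follows this span trend was not tested. The 13 mitochondrially encoded mRNAs had a median of 0.18 (camera adjusted p = 0.197), with mt-Co1 at 0.29 and mt-Nd4 at 0.19, and the median was 0.27 without SRSF1KO replicate 1 and 0.077 without SRSF1KO replicate 2. Glycolysis (21 genes, median −0.06, adjusted p = 0.973), cholesterol synthesis (24 genes, −0.10, adjusted p = 0.628) and the unfolded protein and integrated stress response (31 genes, −0.09, adjusted p = 0.294) did not pass with camera. The stress response median was −0.18 with the replicate block, −0.16 without SRSF1KO replicate 2 and −0.025 at a mean of at least 5 CPM. Slc16a1 stood at 0.26, Ldhb at 0.24, Acat2 at −0.82, Hmgcs1 at −0.47, Xbp1 at 0.62 and Calr at −0.45, and none of these 6 passed. TCRα variable segments summed to 420 ± 16.4 CPM in WT and 422 ± 27.4 CPM in SRSF1KO over 80 genes, and 0 of them were called by edgeR, with 2 higher and 1 lower at an unadjusted p under 0.05.

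In what follows, the within-sex test, the span test and the pseudogene test were set before their results were seen, and the tests of other cell types, maturation stage, splits, Slfn reads and neighbouring genes after. Among the 10 splits of the 5 libraries into 3 and 2, the real one called 46 genes and the highest other one 2, that of WT replicate 2 and SRSF1KO replicate 1, the libraries of the male pattern. So 1 of 10 splits gave as many genes, and a share under 0.05 cannot be reached with so few splits.

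Interferon, class I and maturation genes were lower in SRSF1KO. A difference in sex is argued against by the within-sex medians of the interferon list, −0.36 and −0.93, both below 0. Loss of macrophages and B cells together, which the sort would remove, is argued against by 34 markers outside MHC class II. These pool B cell, macrophage and dendritic cell markers and do not separate the cell types. Their median was 0.24 (bootstrap 95% interval −0.06 to 0.45 over resampled markers), with Ighm at 0.34, Cst3 at −0.07 and Lyz2 at −0.06. That interval treats the markers as independent and does not measure the spread between libraries. The argument from these markers also leans on SRSF1KO replicate 1, without which their median was 0.067 against −0.39 for the interferon list. Markers of at least 5 CPM, at 0.15 ± 0.54 (SD), then reached the interferon value. Ighm held 484 of the 865 CPM that the markers summed to in WT, and whether its reads came from B cells was not measured. Igkc stood at 29.6 ± 22.6 CPM in WT and 45.5 ± 3.19 CPM in SRSF1KO. Fewer dendritic cells, which the sort would also remove, stay open, since the 4 MHC class II genes had a median of −0.45. That median lay between −0.90 and −0.12 with 1 library left out. The class II genes summed to 373 ± 112 CPM in WT while the class I and interferon lists lost 4579 and 1514 CPM. But the share of class II transcripts in such cells was not measured. Outside class II, Xcr1 stood at −6.13 and Siglech at 0.97, both at low levels. Fewer γδ T or NK cells were not tested as a cause. Nkg7 stood at −2.14 and Il2rb at −1.09, while 11 of the 19 markers of these cells were positive. When adjusted over the list alone, 1 of these markers was higher and 3 were lower. Another candidate explanation that stays open is an earlier average stage of the sorted SRSF1KO cells: maturation genes outside the class I list had a median of −0.36 while pre-selection genes were higher, but an estimated correlation ended both calls, and a shift of stage cannot be told apart from a direct effect of SRSF1 on these genes without libraries resolved by stage.

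Ribosomal protein genes were lower in SRSF1KO. Log2 fold changes rose with genomic span across 9682 genes of at least 5 CPM (Spearman 0.18 across genes, which are not independent), from a median of −0.14 in the shortest of 10 bins to 0.09 in the longest, and ribosomal protein genes are short. Genomic span as the whole cause is argued against by 10000 random lists matched on span and expression, with a median of −0.12 against −0.41. Their 95% range was −0.19 to −0.06, and 0 of them lay as low. That range is too narrow to give a chance level, because their genes were drawn singly while ribosomal protein genes move together (estimated correlation 0.72). Transcript length was not matched. Movement of reads to 297 pseudogenes named after a ribosomal protein is argued against by their sum. It moved with the parents, from 262 ± 20.8 to 192 ± 2.8 CPM, a gain of −0.70% of the parents' loss. Pseudogenes under other names were not summed, and reads left uncounted would not show, so loss of reads by those routes cannot be told. Part of the fall, about the size of the matched median, may follow the span trend, and an effect of the genotype on the remainder is a hypothesis.

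Slfn1 was lower and Slfn4 higher in SRSF1KO, and both lie within 5 Mb of Srsf1 on chromosome 11. Reads passing from Slfn1 to Slfn4 are argued against as the cause of the fall, since the gain of Slfn4 was 15.2% of the loss of Slfn1. Their sum fell from 162 ± 9.27 to 53.05 ± 9.18 CPM. A candidate explanation that stays open is a chromosome segment carried along with the floxed Srsf1 allele: 2 of 94 tested genes within 5 Mb were called against 0.278 expected (one-sided Fisher's exact test, p = 0.0315), but both are the pair that prompted the test, and 0 others were called by edgeR. The genetic background of the segment was not measured, so it cannot be told apart from an effect of SRSF1 loss.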
